A study of Homo sapiens with 6 samples.

How the data were processed

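RNA-seq libraries of SKOV-3 cells were compared between a negative control group (NC, 3 libraries) and a group overexpressing LAIR-1 (OE, 3 libraries). Per the labels, total RNA was extracted with Trizol, ribosomal RNA was removed with probes and RNase H, and DNase I treatment followed before libraries were made with a VAHTS Universal V8 kit. The kit's strandedness is not given in the sources used here.

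The values are raw counts per gene, deposited as whole numbers for 60504 Ensembl gene IDs in 6 libraries, with no normalization by the authors. Per the submitters' processing notes, featureCounts 2.0.3 of Subread and the GRCh38 genome were used. The aligner and the annotation release are not given in the sources used here. Per the file headers, each gene has a start, an end and a length, and in all 60504 genes the length equals the distance from start to end. Reads were therefore counted over whole gene spans, introns included. GENCODE release 29 served here for names, biotypes, exons and GC content. It held 56996 of the IDs (94.2%), of which 54241 had the same start and end, so it is close to the annotation the authors used but not the same.

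The counts also show how overlapping genes were handled. All 388 protein-coding genes that lay wholly inside genes on the same strand, all 821 that lay wholly inside genes on the opposite strand, and all 1729 wholly covered by genes on either strand had 0 counts in the 6 libraries, against 1006 of 6970 protein-coding genes (14.4%) that overlapped no other gene. Reads falling in more than 1 gene span were thus not counted, and strand was not used to separate them. A gene partly covered by another is measured only from the rest of its span, and reads of a gene and an antisense partner cannot be told apart by strand. A smaller deposited table of 19797 gene symbols held the same 6 counts as the gene of that name for 18756 symbols, and it was not used for tests.

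The groups, the tests between them, the 33 gene lists and the rule for named genes were chosen before the data were examined. Chosen later were the alternatives said below to have been added, and the gene groups, lists and tests that the closing observations say were picked after values had been seen. Genes were filtered with filterByExpr (minimum count 10), which left 19007, and libraries were scaled with TMM factors. The comparison of OE with NC used edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood test (robust fit, two-sided) and Benjamini-Hochberg adjustment over the 19007 genes at 0.05. Log2 fold changes are OE relative to NC, with the standard error taken from the fold change and its F statistic. CPM are scaled with the TMM factors and given as mean ± SD over 3 libraries. The labels do not say that replicate numbers pair the libraries, and no block was fitted in the reported test.

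There were 33 gene lists, and all 814 of their symbols were matched to gene IDs. Each list was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 33 lists, and again with an estimated correlation. Members were counted as higher or lower by the edgeR adjusted p over all genes and, in a second count, with p adjusted over the list alone. Named genes followed a fixed rule. LAIR1 came before all others. Then came the 10 protein-coding genes with the largest rise and the 10 with the largest fall among genes that passed the test, had a mean of at least 1 CPM and did not overlap between groups. From each list up to 4 passing members with the smallest adjusted p could be named, and up to 2 members of highest CPM that did not pass. Genes named outside this rule are said to have been chosen after their values were seen.

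The alternatives were DESeq2 size factors, upper-quartile scaling or library totals in place of TMM, no low-count filter or a filter at 1 CPM in 3 libraries, DESeq2 1.42.0 or limma-voom in place of edgeR, protein-coding genes alone, the replicate number as a block, each library left out in turn, and fry in place of camera. After the data were seen, 3 further alternatives were added, because fold changes followed gene span. A trend with gene span, or with GC content, was removed from each library by offsets from a lowess curve (span 0.3) of its log2 CPM (prior count 2) around the mean of all libraries. The last of the 3 tested only genes whose exons cover at least 30% of the span. Removing the span trend and estimating the correlation was also run for the lists.

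The depth of 29636366 to 42971250 counts per library puts the level that 3 counts represent at 0.0698 to 0.101 CPM. Intervals and floors cover counting error only. The steps were tested on simulated counts for the 19007 genes of the OE and NC comparison. The test recovered 44.8% of 67 genes changed 1.5-fold, 65.7% of 67 changed 2-fold and 95.5% of 66 changed 4-fold, with 7 calls among 18777 unchanged genes. A list shifted 1.3-fold was called and 0 of 32 random lists were. Genes were simulated independently of each other, so this does not show how often camera calls lists whose members vary together. The estimated correlation in the data reached 0.722, for ribosomal proteins. When a trend with gene span was added to the simulated OE libraries, 728 unchanged genes were called, and 10 were called after the trend was removed.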

Results

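The transcriptome of SKOV-3, a human ovarian adenocarcinoma cell line with high ERBB2 expression, was measured by RNA-seq in 3 NC libraries and in 3 OE libraries overexpressing LAIR-1. LAIR-1 is an inhibitory receptor that binds collagen and is normally carried by leukocytes. The counts summed to 39992798, 42812006 and 32774260 in NC replicates 1, 2 and 3, and to 39570049, 29636366 and 42971250 in OE replicates 1, 2 and 3. Between 23719 and 24941 genes had at least 1 count in a library. Protein-coding genes took 91.5% to 92.5% of the counts, and the 10 most abundant genes took 5.23% to 6.55%. The labels name the libraries as replicates without saying that they came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The biological coefficient of variation was 13.2%.

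The design asks what LAIR-1 overexpression changes in these cells. Any other difference between the NC and OE cells or their handling cannot be told apart from an effect of LAIR-1. LAIR1 itself (ENSG00000167613, GRCh38 chromosome 19, 54351384 to 54370558, minus strand, exons covering 42.1% of the span) had 0, 0 and 2 counts in NC replicates 1, 2 and 3, and 1540, 1020 and 1549 counts in OE replicates 1, 2 and 3. In OE it reached 36.7 ± 2.36 CPM (SD, n = 3), above 67% of the tested genes there. Relative to the totals the OE counts were 2117 times those in NC, with a 95% exact interval of 586 to 17480 from the counting error of the 2 NC counts. The difference passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 1.41e-08). Its paralog LAIR2, a soluble collagen-binding relative that lies nearby on the same chromosome, had 0 counts in NC and 5 in OE.

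With LAIR1 counted, 3171 of 19007 tested genes passed edgeR's test, 1610 higher and 1561 lower in OE, and 339 of them changed at least 2-fold, 135 higher and 204 lower. With upper-quartile scaling the split was 1227 higher and 1936 lower. The 2 groups did not overlap for 6620 genes (34.8%), against 10% by chance for 3 libraries against 3. Protein-coding genes made up 1452 of the rises and 1094 of the falls, while 37 lincRNAs rose and 231 fell. The number of calls depended on the libraries. It was 5496 without NC replicate 1, 1264 without NC replicate 2, 668 without NC replicate 3, 1318 without OE replicate 1 and 681 without OE replicate 2. The number changed at least 2-fold was 626, 189, 160, 201 and 164 without the same libraries in turn. On the axis of largest variance (45.6%) NC replicates 1, 2 and 3 lay at -9.1, -44.3 and -35.8, and OE replicates 1, 2 and 3 at 39.1, 35.7 and 14.4.

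Fold changes followed the length of the gene on the chromosome and its GC content. Among genes with a span under 10 kb, 581 rose and 108 fell, whereas among genes spanning over 300 kb 10 rose and 334 fell. The median log2 fold change went from 0.16 in the shortest class to -0.35 in the longest. Across genes, which are not independent replicates, Spearman's rho between fold change and span was -0.31. It was 0.35 with GC content and 0.33 with the share of the span that exons cover. Within classes of span the mean rho with GC content was 0.29. Genes over 100 kb took 36.0%, 39.9% and 38.5% of the counts in NC replicates 1, 2 and 3, and 33.2%, 32.8% and 34.2% in OE replicates 1, 2 and 3. After the trend with span was removed from each library, 2485 genes passed edgeR's test, 1443 higher and 1042 lower, and 2005 of them were calls in the same direction as before (63.2% of the 3171). After removal of the GC trend 4890 genes passed.

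**Figure D1:**
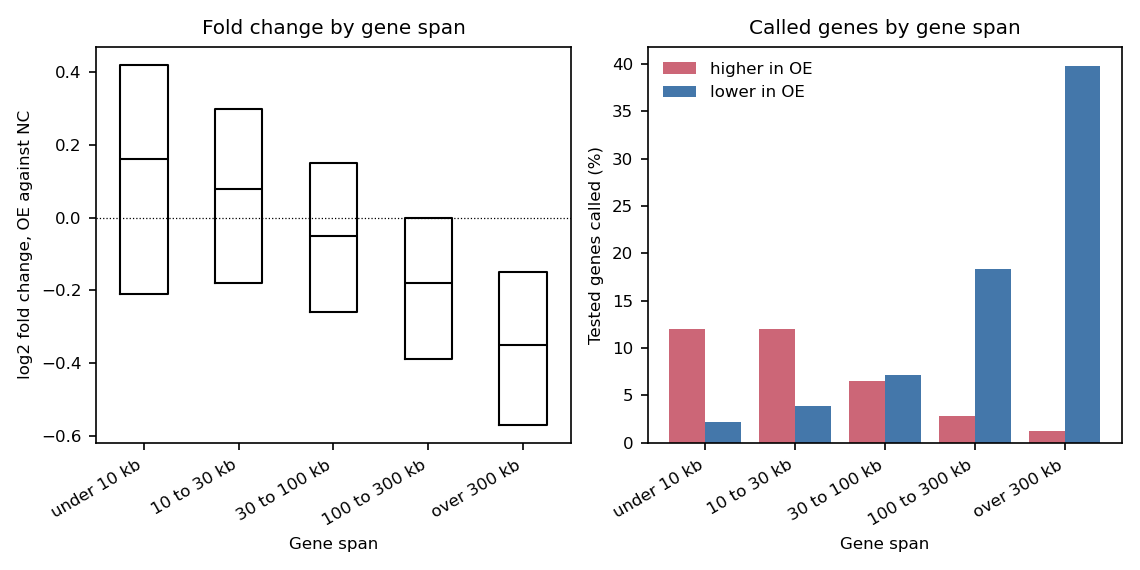
Log2 fold change (OE against NC, left, boxes spanning the interquartile range with a line at the median) and the percent of tested genes that passed the edgeR test (right) in 5 classes of gene span. The median falls from 0.16 under 10 kb to -0.35 over 300 kb, where 39.8% of genes were lower and 1.2% higher in OE.

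The largest rises after LAIR1 included DHRS3, which reduces retinaldehyde to retinol, and ID3, an inhibitor of basic helix-loop-helix transcription factors. DHRS3 went from 5.66 ± 0.222 to 31.1 ± 2.83 CPM (log2 fold change 2.46, SE 0.12, edgeR adjusted p = 2.49e-06) and ID3 from 4.21 ± 0.618 to 20.5 ± 4.89 CPM (2.28, SE 0.19, adjusted p = 0.00015). KRT5, a basal epithelial keratin, rose from 14.4 ± 0.155 to 46.8 ± 7.17 CPM (log2 fold change 1.71), and CHAC1, which degrades glutathione, rose from 21.2 ± 1.24 to 64.3 ± 10.1 CPM (1.60). At lower levels SCEL, a cornified envelope protein, ESM1, a secreted proteoglycan, PPP1R1A, an inhibitor of protein phosphatase 1, and AREG, a ligand of the EGF receptor, rose with log2 fold changes of 2.49, 2.18, 2.07 and 1.82. The other genes in the top 10 were BOLA2B (2.66) and PSG9 (1.83), both uncertain because they have near-identical relatives, and other genes cover 63.8% of the PSG9 span. BOLA2B lost its call without NC replicate 3 or OE replicate 2 (edgeR adjusted p up to 0.0792).

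The largest fall was in KRT17, a keratin of stressed and basal epithelium with known pseudogenes, from 15.0 ± 2.69 to 3.69 ± 1.31 CPM (log2 fold change -2.01, SE 0.23, edgeR adjusted p = 0.000746). ANGPT1, a ligand of the TIE2 receptor, fell from 8.53 ± 1.06 to 2.57 ± 0.217 CPM (-1.74, SE 0.17, adjusted p = 0.000409). NOX4, an NADPH oxidase, the transcription factor CSRNP3, the ephrin receptor EPHA5 and the secretin receptor SCTR fell with log2 fold changes of -1.62, -1.54, -1.49 and -1.42. The protocadherin PCDH15, the secreted semaphorin SEMA3D, the metalloprotease TLL1 and KLHL14 fell with log2 fold changes of -1.41, -1.40, -1.38 and -1.37. Of these genes PCDH15 moved most once the span trend was removed, to -0.82, and it still passed. SCTR did not pass without OE replicate 2 (edgeR adjusted p = 0.0597).

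**Figure D2:**
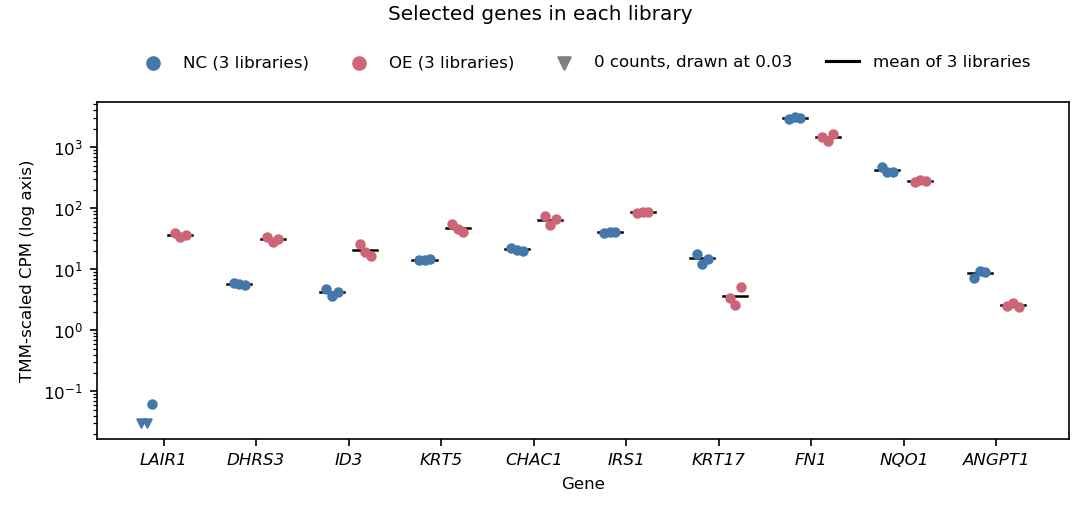
TMM-scaled CPM (log axis) of 10 genes in each NC and OE library, with a bar at the mean of 3 libraries (none drawn for LAIR1 in NC). LAIR1 is at 0 counts in 2 NC libraries (triangles) and at 36.7 ± 2.36 CPM in OE, and FN1 went from 2987 ± 84.2 to 1444 ± 177 CPM.

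Camera called lists of proliferation genes higher in OE at the preset correlation. In the cell cycle and mitosis list 20 of 33 tested members rose and 0 fell (27 and 0 adjusted over the list alone), with a median log2 fold change of 0.44. They included the mitotic kinase PLK1 (0.96), the spindle assembly factor TPX2 (0.74), the anaphase activator CDC20 (0.73) and cyclin B1 (CCNB1, 0.62), while TOP2A did not pass (0.32, edgeR adjusted p = 0.0764). Among DNA replication genes 11 of 33 rose and 0 fell (22 and 0 adjusted over the list alone), including the ribonucleotide reductase subunit RRM2 (0.73), the origin recognition factor ORC6 (0.76) and the helicase subunit MCM7 (0.57). Replication-dependent histones, the chromatin proteins made during DNA synthesis, had the highest median, 0.84, with 29 of 30 members higher (30 adjusted over the list alone). H2BC11 went from 42.6 ± 5.50 to 84.2 ± 7.43 CPM and H2BC13 from 42.2 ± 4.45 to 79.5 ± 5.56 CPM, although histone genes are near-identical and reads can be split among them. The camera adjusted p was 4.68e-15 for cell cycle, 1.19e-08 for DNA replication and 5.7e-32 for histones. With an estimated correlation these became adjusted p = 0.0799, adjusted p = 0.399 and adjusted p = 0.241.

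At the preset correlation camera also called lists of sugar metabolism and of the response to amino acid shortage and misfolded protein higher. In the glycolysis list 14 of 20 members rose and 0 fell (16 and 0 adjusted over the list alone), with a median of 0.51. Hexokinase 2 (HK2) rose by 0.92, aldolase A (ALDOA) by 0.84, and lactate dehydrogenase A (LDHA) from 1516 ± 121 to 2452 ± 125 CPM. In the ATF4 and unfolded protein response list 16 of 28 members rose and 0 fell (17 and 1 adjusted over the list alone), with a median of 0.48. ATF4, the transcription factor of the integrated stress response, went from 280.1 ± 30.02 to 453.9 ± 19.9 CPM, and CEBPB (0.98) and SESN2 (0.82) rose with it, while the cystine transporter SLC7A11 did not pass (-0.42, edgeR adjusted p = 0.0617). The hypoxia list had 6 of 17 members higher and 0 lower (7 and 0 adjusted over the list alone), among them the angiogenic factor VEGFA (0.74) and the carbonic anhydrase CA12 (0.56). Camera gave adjusted p = 1.02e-11 for glycolysis, 1.43e-11 for ATF4 and 0.00393 for hypoxia. With an estimated correlation these became adjusted p = 0.347, adjusted p = 0.207 and adjusted p = 0.207.

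**Figure D3:**
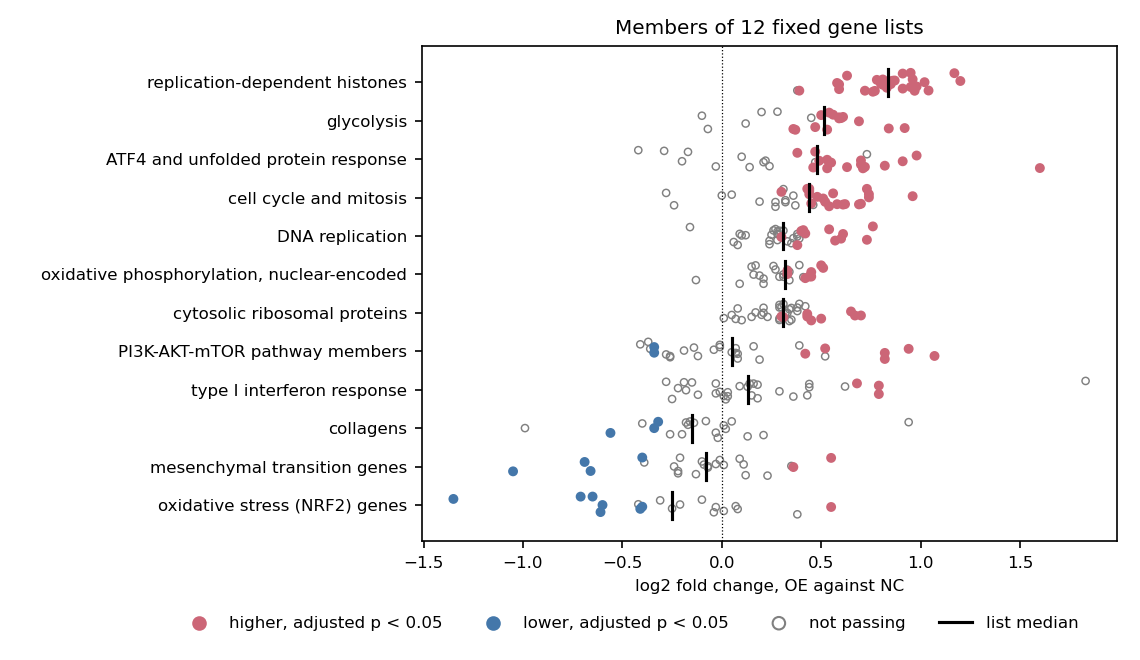
Log2 fold change (OE against NC) of each tested member of 12 of the 33 gene lists, with filled points for members that passed the edgeR test and a bar at the list median. The medians run from 0.84 in histones to -0.25 in the NRF2 list.

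Parts of the translation and respiration machinery rose by smaller amounts. Of 36 cytosolic ribosomal protein genes 9 rose and 0 fell (20 and 0 adjusted over the list alone), with a median of 0.31, and of 26 nuclear-encoded genes of oxidative phosphorylation 8 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 0.32. RPS2 (0.67) and the succinate dehydrogenase subunit SDHB (0.51) were among them. RPS2 lost its call without OE replicate 2 (edgeR adjusted p = 0.055), and SDHB without NC replicate 3 or OE replicate 2 (adjusted p up to 0.0602). Many ribosomal protein genes have processed pseudogenes, so their counts are uncertain. After removal of the span trend 5 ribosomal and 3 oxidative phosphorylation genes passed. Camera gave adjusted p = 1.37e-07 for ribosomal proteins and 3.03e-06 for oxidative phosphorylation, and adjusted p = 0.507 and adjusted p = 0.403 with an estimated correlation. The oxidative phosphorylation list had adjusted p = 0.145 at an exon share of at least 30%. The 13 mitochondrially encoded genes had a median of 0.20, and 0 passed in either direction, also adjusted over the list alone. Camera did not call them (adjusted p = 0.279, but 2.14e-05 without OE replicate 1). The mitochondrial chromosome took 2.08%, 1.90% and 2.08% of the counts in NC replicates 1, 2 and 3 and 1.62%, 2.23% and 2.95% in OE replicates 1, 2 and 3.

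The oxidative stress list of NRF2 targets was the only list of the 33 that camera called lower. Of 19 members 7 fell and 1 rose (9 and 2 adjusted over the list alone), with a median of -0.25 (camera adjusted p = 0.00484, but adjusted p = 0.267 with an estimated correlation). The quinone reductase NQO1 fell from 422.1 ± 39.7 to 278.3 ± 13.3 CPM and GCLC, which makes the precursor of glutathione, from 118.7 ± 12.9 to 75.5 ± 9.44 CPM. The aldo-keto reductase AKR1C2 (-0.71) fell as well, but it has close paralogs, 74.2% of its span is covered by other genes, and its edgeR adjusted p was up to 0.0788 without NC replicate 3, OE replicate 1 or OE replicate 2.

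Genes of epithelial junctions and of the p53 response were also called higher as lists. In the epithelial list 6 of 22 members rose and 0 fell (6 and 0 adjusted over the list alone), among them the keratin KRT18 (0.73), while desmoplakin (DSP) did not pass (0.21, edgeR adjusted p = 0.126). Its camera adjusted p was 0.000992, and adjusted p = 0.267 with an estimated correlation. In the p53 list 5 of 19 members rose and 2 fell (6 and 3 adjusted over the list alone), with the stress cytokine GDF15 (1.34), GADD45A (1.13) and the nuclease AEN (1.01) higher, the antiproliferative gene BTG2 lower (-0.83), and MDM2 at 0.09 (edgeR adjusted p = 0.487). The p53 list had a camera adjusted p of 0.0205, but adjusted p = 0.241 with an estimated correlation, 0.111 after removal of the span trend, 0.0906 after removal of the GC trend, 0.0906 with limma-voom, 0.428 at an exon share of at least 30% and 0.162 without NC replicate 1. GDF15 and GADD45A are also known targets of the ATF4 pathway.

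The list of LAIR family and inhibitory receptor signalling genes was called through LAIR1 itself. LAIR1 was the only one of 8 tested members to rise, and 0 fell (1 and 0 adjusted over the list alone). The camera adjusted p was 2.81e-08, but adjusted p = 0.0799 with an estimated correlation and 0.0986 with limma-voom. Without LAIR1 the other 7 members had a median of 0.12 and an unadjusted camera p of 0.361. The phosphatase SHP-2 (PTPN11), which inhibitory receptors recruit, was at 320.3 ± 11.5 CPM in NC and 315.2 ± 15.0 CPM in OE (edgeR adjusted p = 0.874).

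In the PI3K-AKT-mTOR pathway 6 of 29 members rose and 2 fell (6 and 3 adjusted over the list alone). IRS1, the adaptor of the insulin receptor, went from 40.7 ± 0.931 to 85.5 ± 1.70 CPM (log2 fold change 1.07, SE 0.09, edgeR adjusted p = 0.00015). The others named by the rule, the translation repressor EIF4EBP1 (0.82), SESN2 (0.82) and DDIT4 (0.94), are known to restrain mTOR signalling or its output, and other genes cover 50.4% of DDIT4. Camera did not call the list (adjusted p = 0.14), although it did after removal of the span trend (adjusted p = 0.00147), with no low-count filter (0.0478) and without OE replicate 2 (0.048). With both the trend removed and an estimated correlation the value was adjusted p = 0.26.

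Receptors and proteins of the extracellular matrix went in both directions. Fibronectin (FN1), among the most abundant transcripts, fell from 2987 ± 84.2 to 1444 ± 177 CPM (log2 fold change -1.05, SE 0.10, edgeR adjusted p = 0.000445), while the protease MMP7 rose by 0.95. In the matrix list 5 of 25 members rose and 3 fell (8 and 5 adjusted over the list alone, camera adjusted p = 0.413). Among 14 integrins 3 rose and 3 fell (3 and 5 adjusted over the list alone, camera adjusted p = 0.63), with ITGB6 at -0.79, ITGA3 at 0.71 and ITGA6 at 0.50. Of 20 collagens, the ligands of LAIR-1, 0 rose and 3 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.176). The list was called lower after removal of the GC trend (adjusted p = 0.00103) and without OE replicate 1 (0.0443). The 3 that fell were COL4A5 (-0.56), COL12A1 (-0.34) and COL27A1 (-0.32), all of which stopped passing after removal of the span trend (edgeR adjusted p = 0.0653, 0.176 and 0.449), and each lost its call without NC replicate 3 (adjusted p up to 0.0561, 0.165 and 0.15 over the libraries left out). Among 24 mesenchymal genes 2 rose and 4 fell (2 and 4 adjusted over the list alone, camera adjusted p = 0.0984), including falls of CCN2 (-0.69) and TAGLN (-0.66), and vimentin (VIM) was at -0.07 (edgeR adjusted p = 0.71). Camera called the mesenchymal list lower with no low-count filter (adjusted p = 0.0478), with protein-coding genes alone (0.0448), after removal of the GC trend (0.012) and at an exon share of at least 30% (0.0135).

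Signalling and inflammatory lists held single genes that changed, but camera called none of them as lists. Of 21 immediate early genes 7 rose and 4 fell (8 and 5 adjusted over the list alone, camera adjusted p = 0.176), with MYC (0.79), SPRY4 (0.79) and FOSL1 (0.80) higher and the stress factor ATF3 lower (-1.07). In the Wnt, Notch and Hippo list 5 of 21 rose and 2 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.263), and the secreted Wnt antagonist DKK1 went from 7.02 ± 0.141 to 20.1 ± 2.01 CPM. Of 24 NF-kB and cytokine genes 4 rose and 0 fell (4 and 0 adjusted over the list alone, camera adjusted p = 0.176, and 0.0169 without OE replicate 2), among them the chemokine CXCL1 (0.70). Of 31 interferon genes 3 rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.131), led by IFI27 (0.79). That list was called higher with no low-count filter (0.0478) and after removal of the GC trend (0.0411). Of 17 antigen presentation genes 2 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.0786). That last value was 0.0255 with no low-count filter, 0.0406 with limma-voom, 0.0348 without NC replicate 1, 0.048 without OE replicate 2 and 0.0442 without OE replicate 3.

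In the reported test camera did not call the lists of cell survival, chaperones, lipids and drug transport either. Among 29 apoptosis regulators 4 rose and 1 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.264), with the pro-apoptotic BMF lower (-0.97) and the anti-apoptotic BCL2L1 higher (0.55). Of 15 heat shock genes 3 rose and 2 fell (5 and 3 adjusted over the list alone, camera adjusted p = 0.531), with HSP90AA1 higher (0.63) and HSPA1B lower (-0.87), a gene whose reads are shared with the near-identical HSPA1A. Camera called the heat shock list lower at an exon share of at least 30% (adjusted p = 0.011). Cholesterol synthesis had 3 of 24 members higher and 1 lower (3 and 1 adjusted over the list alone, camera adjusted p = 0.131, and 0.0392 with no low-count filter). Fatty acid synthesis and oxidation had 4 of 23 higher and 1 lower (4 and 1 adjusted over the list alone, camera adjusted p = 0.24, and 0.0265 after removal of the span trend). Among 11 drug transporters the efflux pump ABCC3 fell (-0.60, edgeR adjusted p = 0.0028) and 0 rose (1 and 0 adjusted over the list alone, camera adjusted p = 0.131).

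The remaining lists described the cell line, other cell types and RNA classes. Of 17 ovarian cancer and SKOV-3 markers 2 rose and 2 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.851), and ERBB2 was at 8350 ± 1267 CPM in NC and 9403 ± 772 CPM in OE (edgeR adjusted p = 0.338). The oestrogen receptor gene ESR1 fell (-0.53) but did not pass after removal of the span trend (-0.17, edgeR adjusted p = 0.11) or without OE replicate 2 or NC replicate 3 (up to 0.0533). Of 8 leukocyte markers above the filter 2 rose and 2 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.851). Of 12 fibroblast and endothelial markers 3 rose and 0 fell (3 and 0 adjusted over the list alone). That list had a median of -0.17 but a mean of 0.10, and camera gave the direction up (adjusted p = 0.413). The endothelial receptor KDR in it rose from 1.11 ± 0.192 to 3.13 ± 0.149 CPM. Of 5 structural RNAs of RNA polymerase III and similar genes 0 passed, also adjusted over the list alone (camera adjusted p = 0.58). Of 8 nuclear-retained RNAs 1 rose and 2 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.413), with NEAT1 at -0.57, SNHG1 at 0.77 and MALAT1 at -0.22 (edgeR adjusted p = 0.197).

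In all, camera called 12 of the 33 lists, 11 higher and 1 lower, and 11 of them were called in the same direction after removal of the span trend. With an estimated correlation 0 of the 33 were called by camera, while 6 had an unadjusted p under 0.05, and fry called 15. Fry tests whether the members of a list move one way, without comparing them with other genes. It did not call ribosomal proteins (adjusted p = 0.123) or oxidative phosphorylation (0.05), and besides the other 10 it called the lists of apoptosis (0.043), mesenchymal genes (0.0367), interferon (0.0104), fatty acids (0.0213) and drug transporters (0.00336). Of 127 named genes other than LAIR1 that passed the edgeR test, 73 passed in each fit that left out 1 library. The other 54 lost their call in at least 1 of these fits, 50 of them without NC replicate 3 and 46 without OE replicate 2.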

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

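The alternatives that removed a trend with gene span or GC content, or kept only genes with a high exon share, were chosen after the data were seen, and the others were planned. LAIR1 passed in each of them. The number of genes passing the test stayed within 1.5 times of 3171 under the other scalings, the other filters, limma-voom (2937), DESeq2 (4043, with no adjusted p for 13338 genes), protein-coding genes only (2521) and removal of the span trend (2485). It was 4890 once the GC trend was removed, and the cause was not tested. It was 424, with 79 changed at least 2-fold, when only the 5346 genes with an exon share of at least 30% entered. Of 21 genes (LAIR1 and the 20 of largest change) 7 passed in that fit, and the others had a lower exon share and were not tested. The share of tested genes that passed was 7.9% in that fit, against 16.7%, and the cause was not tested. Protein-coding genes alone gave 194 changed at least 2-fold, from 13886 genes tested. Leaving out 1 library gave 668 (NC replicate 3) to 5496 (NC replicate 1) genes, 160 to 626 of them at least 2-fold by the same libraries, and the cause was not tested. With the replicate number as a block 5713 genes passed. The deviations of same-numbered libraries from their group means correlated at 0.67, -0.12 and 0.28, and NC replicate 2 correlated best with OE replicate 3 (0.71). Deviations from a mean of 3 libraries depend on each other, so these values cannot decide whether the numbers pair the libraries. Camera called 12 lists, and 0 with an estimated correlation in place of the preset 0.01, with or without the span trend. Under the remaining alternatives 10 to 17 lists were called, and 8 to 12 of the 12 kept their call and direction. The 8 was at an exon share of at least 30%, where 2 lists lost their call and the other lists not kept had no value. The 17, with no low-count filter, held all 12 and 5 more. The p53 list had an adjusted p of 0.0551 with the replicate block. The heat shock list, not called otherwise, was called lower with an adjusted p of 0.011 at an exon share of at least 30%, and the cause was not tested. No other list or named gene turned its direction while called. Among named genes, 17 lost their call with the span trend removed and 4 with the GC trend removed. The lost calls under the other scalings numbered 5 at most. Small changes can be missed, since 44.8% of simulated 1.5-fold changes were recovered at this depth, spread and number of libraries, which were not varied. In that simulation 18777 of 19007 genes were unchanged. The share recovered at an adjusted p depends on this number, so it can differ in the reported test.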

Other observations

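The gene groups here were picked after their leading members had been seen, as were the tests of unspliced RNA and of mixing below. The set tests of 4 such lists left out the members recorded as seen when the lists were written. Some of the members used, among them HEY1, TNFAIP2 and KRT18, also belong to fixed lists tested above and may have been seen there. Of the inhibitors of basic helix-loop-helix factors ID1, ID2 and ID3 were higher in OE, while ID4 did not pass (0.56, edgeR adjusted p = 0.328), and ID1 went from 135.5 ± 29.7 to 344.2 ± 89.9 CPM (log2 fold change 1.34, edgeR adjusted p = 0.00208). Ligands of the EGF receptor rose in part, with AREG at 1.82, EREG at 1.45, HBEGF at 0.67 and TGFA at 0.33, while EGF itself did not pass (-0.49, edgeR adjusted p = 0.0855). The 5 ligands not recorded as seen before were not called as a set (camera p of 0.328, and 0.437 adjusted over the 4 lists). The keratins KRT18 (0.73) and KRT19 (0.67) rose with KRT5, and KRT17 fell. Of 9 keratins not recorded as seen before 4 rose and 0 fell, and they were called as a set (camera p adjusted over the 4 lists of 0.0052, and 0.0306 after removal of the span trend), but not with an estimated correlation (adjusted p = 0.276). KRT7, KRT8, KRT18 and KRT19 in this set also belong to the epithelial list, so the keratin call partly repeats the call of that list. The metallothionein MT2A, a metal-binding protein, went from 26.9 ± 11.7 to 78.9 ± 9.69 CPM. The placental glycoprotein genes PSG4 (1.28), PSG5 (1.45) and PSG9 (1.83) rose, with reads that close paralogs can share.

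DHRS3, TGM2 and PLAAT4, known targets of retinoic acid, rose with log2 fold changes of 2.46, 1.21 and 1.17, and higher retinoic acid signalling was tested as a hypothesis. The other 13 tested targets did not rise as a set (unadjusted camera p of 0.632), with RARA (0.58), HOXB2 (0.58) and TNFAIP2 (0.49) higher but MEIS1 (-0.49) and MEIS2 (-0.44) lower. MEIS2 did not pass after removal of the span trend (edgeR adjusted p = 0.121). TNFAIP2 lost its call in some of the fits that left out 1 library (edgeR adjusted p up to 0.069). The rise of ID2 and ID3 led to a second hypothesis, higher BMP and SMAD signalling. Its 11 other tested targets rose as a set (unadjusted camera p of 0.00333, and 0.00666 adjusted over the 4 lists of this kind), 4 of them higher, ID1, SMAD6, MSX1 and HEY1, and SMAD7 lower (-0.52). Adjusted over the 4 lists, the p was 0.0346 after removal of the span trend, but 0.148 with an estimated correlation (0.037 unadjusted), which ended the call. At the preset correlation the data are consistent with such a change, which may equally reflect other regulators of these genes, and no protein or phosphorylation was measured.

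Genes of long span were lower in OE. The trend with span does not account for all of the calls, since 63.2% kept their call and direction once it was removed. A GC trend is not the whole cause of it either, because rho with span was still -0.23 after the GC trend had been removed. Nor does span account for the trend with GC content, whose rho was 0.27 after removal of the span trend. A lower share of unspliced or nuclear RNA in OE may contribute. At matched span the mean rho of fold change with exon share was 0.12, from 0.01 to 0.19 over 10 span classes, but intron and exon reads are summed in the counts, so RNA processing and a change in the expression of long genes cannot be told apart.

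NC replicate 1 lay 47.7% of the way from the other NC libraries to OE, and OE replicate 3 was the OE library nearest to NC. RNA or cells of the OE group in NC replicate 1 would have brought about 696 LAIR1 counts, and 0 were found. The span trend does not set this position, which was 45.2% after its removal. Other differences in how the cultures or libraries were handled are not recorded in the labels, and no biological explanation was tested.

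There are 10 ways to split the 6 libraries 3 against 3, too few for a share under 0.05. The real split gave 3171 genes and 339 changed at least 2-fold, and 1 of the 10 splits, the real one, gave as many of each. The highest of the others was 0 for both by edgeR. Each of these puts NC and OE libraries into the same group, which widens the spread within groups. The 0 therefore says nothing about what caused the difference between NC and OE. At an unadjusted edgeR p under 0.05 the real split gave 6268 genes. Among the other splits the highest was 4111, when NC replicate 1 was grouped with OE replicates 1 and 2, a sign of structure among the libraries. For gene lists the real split gave 12 called lists, again 1 of 10, with the LAIR list called through LAIR1 among them. The other splits each gave 4 to 9 called lists, although edgeR called 0 genes in them. Camera at the preset correlation thus called lists also where the groups were mixed.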
